A study of Escherichia coli K-12 and Escherichia coli BW25113 with 3 samples.

How the data were processed

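RNA was sequenced from 3 cultures of Escherichia coli K-12, with 1 library per group. The wild type group was strain BW25113 with the empty plasmid pBluescriptSK+. The dam deletion vector group was strain JW3350, a BW25113 derivative lacking dam, with the same empty plasmid. The dam deletion dnd group was JW3350 with the plasmid pJTU1238, which per the labels expresses the Salmonella genes dndBCDE. Per the labels' protocols, cells were in log phase in LB medium, RNA was isolated with TRIzol, ribosomal RNA was depleted with Ribo-Zero and libraries were made with a TruSeq kit.

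Each deposited file gave an expected count and an FPKM value (fragments per kilobase of gene length, scaled by library size) for each gene of 1 library, per the file headers. Bowtie2, RSEM and edgeR are named in the submitters' processing notes, and their versions, their roles and the genome build are not given in the sources used here. The deposited expected counts were not scaled by library, and most were whole numbers. A total of 91 genes had a count that was not whole, within 0.001, in at least 1 library. This was read as reads matching several copies being divided between them, though the sources used here do not say so. Such multi-copy genes were treated as uncertain. The authors' FPKM values were scaled to a library size that is not stated. Count over FPKM as a line in gene length gave 9039936 for the wild type library, 13419937 for the dam deletion vector library and 8594626 for the dnd library, which is 0.946, 1.25 and 0.981 times the total of the count column. The FPKM values therefore served only as an alternative to the counts. Whether counting used the strand of the reads is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated.

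Each file listed the same 4654 features, of which 4652 were chromosomal genes with BW25113 locus tags and 2 were plasmid sequences. Gene symbols came from the descriptions in the files, matched by protein hit or by listed symbol and by gene length to the RefSeq gene table of K-12 strain MG1655 (assembly ASM584v2), which was used for names only. A symbol was given to 3017 genes, and 33 of these matched in length only within 10 percent. The remaining 1635 genes kept their locus tag. No rRNA or tRNA gene was among the named ones.

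Expected counts were rounded to whole numbers. Libraries were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3) computed on the chromosomal genes of the 3 libraries. The plasmid sequences were left out of the scaling and of the comparisons, because the third group carries another plasmid per the labels. The TMM factors were 0.914 for the wild type library, 1.15 for the dam deletion vector library and 0.951 for the dnd library, giving effective sizes of 7153160, 11064934 and 8294165 reads. Levels are given as CPM, the count scaled by the effective library size. For each gene the log2 ratio was computed with a prior count of 0.5 scaled to library size, with an exact conditional binomial (Clopper-Pearson) 95% interval. A gene counted as measured in a comparison if its summed count in both libraries was at least 50. It was called higher or lower if its log2 ratio was at least 1 in size, which is 2-fold, and its interval excluded equal levels. With 1 library per group no p-value was computed. These calls compare libraries, not conditions. The intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

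A collection of 39 gene lists was fixed. The median log2 ratio of each list was set against 10000 random lists of the same size, matched in 20 bins of mean expression, and its percentile describes these libraries. Random lists drew each gene independently, whereas genes of a list often moved together in these libraries. An extreme percentile is therefore not a measure of chance. Lists with fewer than 3 measured members got no percentile. For the genes called in the dam deletion vector library, a gene was said to return if the dnd library was nearer to the wild type library by at least 50 percent of the log2 difference. The same count was made in 100 simulations in which the dnd and dam deletion vector libraries had equal levels, and in 100 in which the 3 libraries had equal levels. These were run with counting error alone or with coefficients of variation of 0.1, 0.2 and 0.4 between libraries. Each gene was drawn independently of the others. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

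The groups, the comparisons and their tests, the gene lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. The tests that weigh explanations were chosen afterwards. The rule named dam and the genes of its operon, the 8 genes with the largest and the 8 with the smallest log2 ratio among those called (3 and 3 for the dnd library against the wild type library), and up to 4 members with the largest absolute log2 ratio of each list described. Stable RNA genes and multi-copy insertion sequences were not taken by size. Which lists to describe was chosen after their values were seen, and genes named outside the rule are marked as such.

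The computation was tested on simulated counts for the 4652 genes, with 50 genes changed at each fold. At 4-fold and at 8-fold, 100 percent of the changed genes were called in each of the 3 comparisons. At 2-fold, which lies on the threshold, 48 percent were called for the dam deletion vector library against the wild type library and 60 percent in each of the other comparisons. At 1.5-fold, the shares were 2, 2 and 4 percent. Among unchanged measured genes, 4 of 3633, 3 of 3622 and 1 of 3524 were called. These simulated counts held counting error only, so these shares are not the rate of false calls between single cultures. In the simulations with all 3 libraries at equal levels, coefficients of variation of 0.2 and 0.4 called 99.95 and 923.5 genes on average. Of 200 random lists of independently drawn genes, 14, 9 and 9 lay outside the middle 95 percent.

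The alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, other minimum counts, prior counts and fold thresholds, a whole interval beyond 2-fold, and the deposited FPKM values as log2(value + 1) or log2(value + 0.1). Scaling with the plasmid sequences included and TMM over genes with a summed count of at least 50 were added after the data were seen. A planned look at sequence motifs upstream of genes was not made, since no genome was used here.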

Results

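Transcript levels were measured by RNA-seq in log-phase Escherichia coli K-12 cultures that, per the labels, differed in genes for DNA modification. The modification itself was not measured. Dam is the DNA adenine methyltransferase that methylates the adenine of GATC sites, and the dnd genes place sulfur in the DNA backbone as a phosphorothioate. The design had 3 groups of 1 library each, namely wild type with an empty vector, a dam deletion with the empty vector, and the dam deletion with a plasmid carrying Salmonella dndBCDE. Reads on chromosomal genes summed to 7828805 in the wild type library, 9615298 in the dam deletion vector library and 8720897 in the dnd library, and 4472, 4531 and 4502 of the 4652 genes had at least 1 read. A count of 3 reads corresponded to 0.419, 0.271 and 0.362 CPM (counts scaled by effective library size). The 10 most abundant genes took 16.7, 16.5 and 13.0 percent of the reads. Because each group had 1 library, none of the differences has a replicate check, and all intervals cover counting error only.

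The dam transcript itself was counted to check the labels. The dam gene had 662 reads in the wild type library, 27 in the dam deletion vector library and 51 in the dnd library, or 92.5, 2.44 and 6.15 CPM. It was 37.1-fold lower in the dam deletion vector library than in wild type (log2 ratio -5.21, interval -5.86 to -4.69) and 14.9-fold lower in the dnd library (-3.90, interval -4.35 to -3.50). Between the deletion libraries the few remaining dam reads differed by a log2 ratio of 1.32 (interval 0.63 to 2.06). Downstream of dam in its operon, rpe (ribulose-phosphate epimerase), gph (phosphoglycolate phosphatase) and trpS (tryptophanyl-tRNA synthetase) were lower in the dam deletion vector library, with log2 ratios of -1.57, -1.69 and -1.35. Upstream of dam, aroK and aroB of the shikimate pathway and damX were not past the rule, at -0.33, -0.64 and -0.21. The dnd library gave nearly the same values against wild type for rpe (-1.44), gph (-1.62) and trpS (-1.41), while aroK, aroB and damX were at 0.79, 0.39 and 0.31. With plasmid reads included in the total count, trpS was no longer past the rule without dnd.

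**Figure D1:**
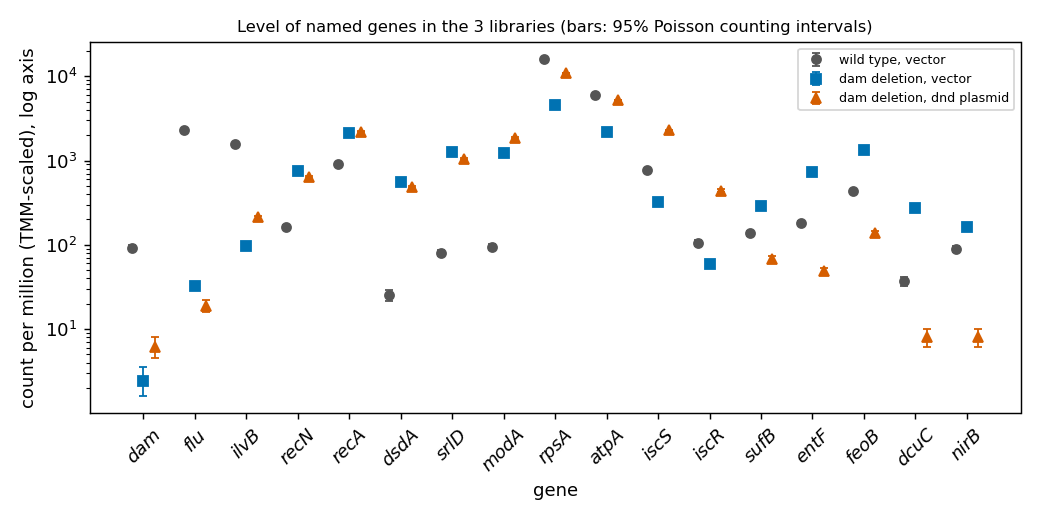
Levels of 17 genes in the 3 libraries, in CPM on a log axis, with 95% Poisson counting intervals as bars and 1 symbol per library. flu was at 2313 CPM in wild type and at 32.6 and 18.8 in the dam deletion libraries, whereas recA was at 912, 2126 and 2204, and iscS at 780, 318 and 2271; sufB was added after its values were seen.

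The dam deletion vector library was compared with the wild type library to see which transcripts differ when dam is missing and the plasmid is the same. In the dam deletion vector library, 16 of 28 genes of the SOS response to DNA damage, 18 of 36 of iron uptake and 8 of 20 of general stress were called higher and 0 lower. The 4 srl genes of sorbitol use were among the 8 highest ratios. The adhesin gene flu, the acetohydroxy acid synthase genes ilvB and ilvN of branched-chain amino acid synthesis, the fimbrial gene fimA and 42 of 50 ribosomal protein genes were lower. flu, which encodes the phase-variable surface adhesin antigen 43, was 70.8-fold lower (log2 ratio -6.14, interval -6.30 to -6.00), the lowest ratio among the called genes. recN, a DNA break repair gene of the SOS response, was 4.59-fold higher, and ribosomal protein genes had a median 2.51-fold lower. Of these lists, only the SOS genes kept their median in the dnd library, which also lacks dam, at 1.06 against wild type. There the medians were -0.87 for iron uptake, -0.07 for general stress and -0.13 for ribosomal proteins, while flu was again lower (-6.94). Of 3821 genes measured between the dam deletion vector and wild type libraries, 352 were called higher and 402 lower, together 19.7 percent. Past 4-fold were 96 genes.

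This split depended on the scaling. With total counts it was 653 higher and 200 lower, because that scaling moved the median of all genes by 0.33 on the log2 scale. With plasmid reads included in the total it was 829 and 151, with a shift of 0.46.

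Beyond flu and dam, the lowest ratios belonged to flgB of the flagellar rod (-4.56, from 70 to 4 reads), BW25113_RS10095 (-4.44, listed as a membrane protein of a sulfur transport family), BW25113_RS10100 (-4.26, hypothetical), ilvN (-4.17), ilvB (from 1566 to 97.8 CPM) and yeeR of the CP4-44 prophage (-3.65). The highest ratio was that of BW25113_RS15575, a hypothetical gene that went from 8 reads in the wild type library to 1536 (6.89, interval 5.97 to 8.17). It was followed by dsdA, the D-serine dehydratase gene, which was 21.9-fold higher (4.45, interval 4.24 to 4.68). The genes srlD, srlB, srlA and srlE for sorbitol uptake and oxidation were higher by 3.98, 3.45, 3.33 and 3.28. Also among the 8 highest were modA, which encodes the molybdate-binding protein (3.71, from 94.1 to 1231 CPM), and deoA, the thymidine phosphorylase gene (3.36).

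Among 28 measured SOS genes, 16 were higher, 0 were lower and 12 were not past the rule. Their median log2 ratio was 1.07, at percentile 100 of matched random lists. recN had the largest ratio (2.20, interval 2.11 to 2.29, from 162 to 746 CPM), ahead of the toxin-antitoxin genes yafN (1.84) and yafO (1.81) and the RecA modulator recX (1.71). Of 16 recombination repair genes, recN and the strand exchange gene recA (1.22, from 912 to 2126 CPM) were higher, the primosomal gene priB (-1.22) and recF (-1.20) were lower, and 12 were not past the rule. The median of that list was -0.23 at percentile 24.2, and total counts, which shift all genes alike, turned its sign at the same percentile. The replication initiation and mismatch repair list had 0 of 13 members higher and 3 lower. Those were recF, mnmG (-1.08), a tRNA modification gene beside the replication origin, and the sliding clamp gene dnaN (-1.05). The initiator gene dnaA was at -0.83, not past the rule, and the median of -0.09 (percentile 42.4) turned in the same way. The calls for priB, recF, mnmG and dnaN were each lost under at least 1 alternative.

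Of 13 measured adhesion genes, 7 were lower and 0 were higher, with a median of -1.13 at percentile 0 (4 lower with plasmid reads in the total count). Besides flu these included fimA, the major subunit of type 1 fimbriae (-2.07, from 724 to 172 CPM), the chaperone gene fimC (-1.92) and the usher gene fimD (-1.48). Flagella and chemotaxis genes were lower in 14 of 33 cases and higher in 0, with a median of -0.45 at percentile 0.01. With plasmid reads in the total count, which shifts all genes alike, the median was 0.0015 at the same percentile. Their counts were low, and with a summed count of at least 200 only 1 gene was lower, the median was -0.22 and the percentile 6.76, inside the middle 95 percent. With FPKM values 8 were lower. Examples were the flagellar sigma factor gene fliA (78 against 11 reads, -3.39), flgD (-3.00) and flgE (-2.88). Branched-chain amino acid synthesis had 5 of 13 members lower and 0 higher, with a median of -0.90 at percentile 0.02. ilvG (from 571 to 143 CPM) and ilvC (-1.92) followed ilvN and ilvB.

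Iron uptake genes under the repressor Fur were higher in 18 of 36 cases and lower in 0, with a median of 0.97 at percentile 100. nrdF, of the manganese-dependent ribonucleotide reductase, was higher by 2.06, the enterobactin synthesis genes entF and entD by 2.03 and 1.65, and the ferrous iron transporter gene feoB by 1.62. General stress genes of the sigma factor RpoS had 8 of 20 members higher and 0 lower (median 0.77, percentile 100), among them osmC (1.56), poxB (1.45), aidB (1.44) and elaB (1.25). With total counts 15 were higher. The sugar and carbon uptake list was mixed, with 15 of 61 members higher and 7 lower, a median of 0.19 at percentile 99.9, and the 4 srl genes on top.

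Ribosomal protein genes were lower in 42 of 50 cases and higher in 0, with a median of -1.33 at percentile 0. rplA (-1.84), rpsA (-1.78), rpsB (-1.74) and rpmE (-1.74) lay at the low end, and rplA went from 5682 to 1592 CPM. ATP synthase genes were lower in 5 of 9 cases (median -1.09) at percentile 2.54, just inside the middle 95 percent, among them atpA (-1.49), atpD (-1.28), atpG (-1.24) and atpC (-1.11), of which the last 3 lost their call under at least 1 alternative. With total counts 25 ribosomal protein genes and 1 ATP synthase gene were lower, and with plasmid reads in the total 13 and 1. The ATP synthase list lay outside the middle 95 percent with a summed count of at least 200 (percentile 2.42) and with FPKM values (2.26). Both medians kept their sign under every scaling run. The ribosomal protein list kept its percentile of 0, which a scaling leaves in place because it shifts the random lists alike.

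**Figure D2:**
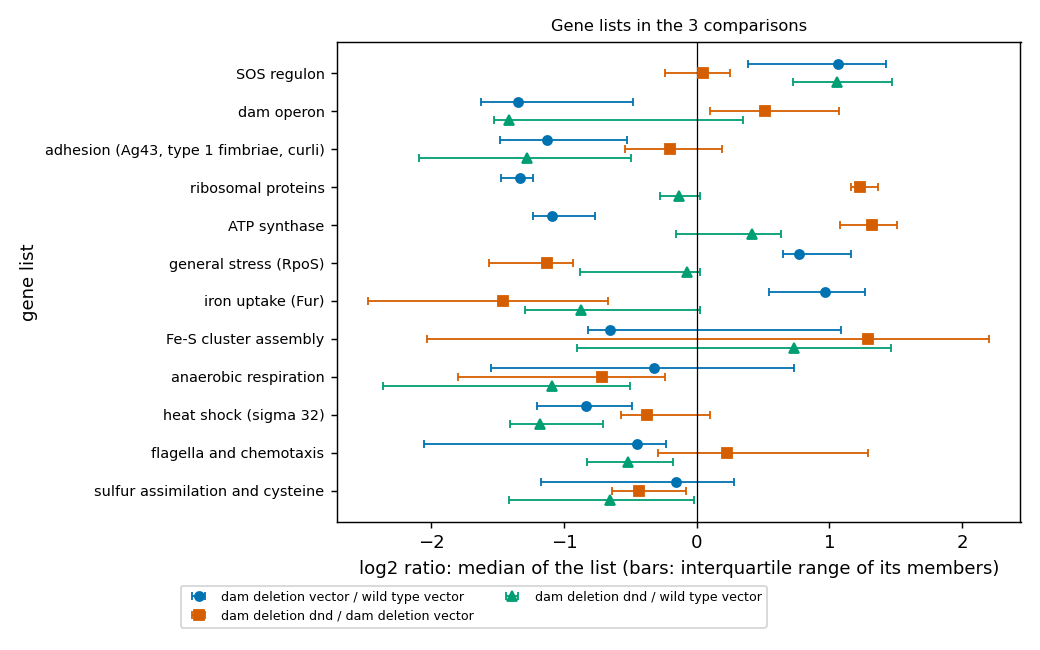
Median log2 ratio of 12 gene lists in the 3 comparisons, with the interquartile range of the members as bars; points right of 0 are higher in the library named first. Ribosomal protein genes lay at -1.33 and 1.23 in the comparisons with the dam deletion vector library, and the medians of SOS genes with the dnd plasmid, flagella in both comparisons with the dam deletion vector library and ribosomal proteins between dnd and wild type changed sign under scalings that move all genes together.

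The dnd library was compared with the dam deletion vector library to see which transcripts differ when cells lacking Dam carry the plasmid that per the labels expresses dndBCDE, whose own transcripts were not measured separately. The isc operon, the housekeeping pathway for iron-sulfur clusters, was higher with the dnd plasmid, and so were 49 of 50 ribosomal protein genes and all 9 ATP synthase genes. The suf operon, the alternative iron-sulfur pathway of stress and iron limitation, was lower, as were 25 of 36 genes of iron uptake, 13 of 20 of general stress and 9 of 28 of anaerobic respiration. iscS, the cysteine desulfurase gene, was 7.15-fold higher (log2 ratio 2.84, interval 2.79 to 2.89, from 318 to 2271 CPM), whereas the enterobactin gene entF was 15.3-fold lower. Of 28 SOS genes, 27 were not past the rule. Of 3823 measured genes, 392 were called higher and 379 lower, together 20.2 percent, with 106 past 4-fold.

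With total counts the split was 216 higher and 637 lower, with a shift of -0.27 in the median of all genes, and with plasmid reads included it was 310 and 476, with a shift of -0.12. With the deposited FPKM values it was 581 and 217, with a shift of 0.22. Past 4-fold, 28 genes were higher and 78 lower.

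All 15 measured genes of iron-sulfur cluster assembly were past the rule, 9 higher and 6 lower, so that their median of 1.29 (percentile 100) describes a mixture. The highest were the co-chaperone gene hscB (2.98, interval 2.83 to 3.14), the regulator gene iscR (2.88), iscS and the scaffold gene iscU (2.33). The 6 lower genes were the suf operon, with a median of -2.11 and a range of -2.26 to -1.74. sufB, named here after its values were seen, was at -2.10. Among 36 iron uptake genes, 25 were lower and 1 was higher, with a median of -1.46 at percentile 0. feoA (-4.12) and feoB (-3.25) of ferrous iron transport and entF (-3.94) and entB (-3.68) of enterobactin synthesis had the largest ratios. The higher gene was ftnA (2.09), named after its value was seen, which is on the list though it encodes the iron store ferritin and not an uptake protein.

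None of the 21 measured genes of sulfur assimilation and cysteine synthesis was past the rule with TMM scaling, against 3 lower with total counts and 1 higher with FPKM values. Their median was -0.44 at percentile 6.75, and -0.096 at percentile 10.3 with FPKM values. The 4 largest ratios were those of cysQ (-0.89), tauD (-0.79), the sulfate-binding protein gene sbp (-0.78) and the serine acetyltransferase gene cysE (0.78).

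Ribosomal protein genes were higher in 49 of 50 cases and lower in 0 (median 1.23, percentile 100), with rpsT (2.13), rpsU (2.04), rpmH (4.01-fold) and rpmA (1.93) on top. All 9 ATP synthase genes were higher (median 1.32, percentile 99.9), including atpB (1.71), atpI (1.55), atpH (1.51) and atpF (1.41). Purine synthesis genes were higher in 7 of 15 cases and lower in 0 (median 0.99, percentile 100), among them purE (1.89), purM (1.81), purK (1.56) and the repressor gene purR (1.32). With total counts 20 ribosomal protein, 5 ATP synthase and 4 purine synthesis genes were higher. The 3 percentiles were the same, as total counts shift all genes alike.

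General stress genes had 13 of 20 members lower and 0 higher (median -1.13, percentile 0), with 7 lower with FPKM values. At the low end were wrbA (-2.81), uspB (-2.03), osmC (-1.76) and bolA (-1.69). Against wild type, the general stress list of the dnd library had a median of -0.07 at percentile 26.6, with 4 of 20 lower and 0 higher. Anaerobic respiration genes were lower in 9 of 28 cases and higher in 0 (median -0.71, percentile 0.01). The succinate exporter gene dcuC was 34.1-fold lower (-5.09, interval -5.48 to -4.75). Next were nirB of nitrite reductase (-4.34), the nitrate transporter gene narK (-3.69) and napF (-2.86). Against wild type, dcuC was at 2.89 in the dam deletion vector library and at -2.20 in the dnd library. Flagella genes were higher in 10 of 32 cases and lower in 1, with a median of 0.23 at percentile 99.9. With total counts, which shift all genes alike, the median was -0.04 at the same percentile. With a summed count of at least 200, 0 genes were higher, the median was -0.15 and the percentile 64.7, and with FPKM values 3 were higher at percentile 94.1, whereas a summed count of at least 10 gave 16 higher. flgG (2.34), fliA (2.26), flgE (2.10) and flgF (1.81) were its largest ratios. Of 28 SOS genes, 1 was higher, the helicase gene uvrD (1.07), and its call was lost under at least 1 alternative. dinI (0.69), ruvB (0.63) and polB (-0.61) were not past the rule, and the SOS median of 0.04 (percentile 45.8) changed sign with total counts and with upper-quartile factors, which shift all genes alike.

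Among the 8 highest genes were also ndk of nucleotide synthesis (2.61), suhB, an inositol monophosphatase gene (2.45), trhO, listed as a rhodanese-related sulfurtransferase (2.44), BW25113_RS15265, hypothetical (2.73, from 13 to 67 reads), and BW25113_RS10525, listed as a putrescine and spermidine transporter (2.65). The lowest ratio was that of ubiU (-5.35, 40.9-fold lower), which acts in ubiquinone synthesis without oxygen. Against wild type, ubiU was at 1.90 in the dam deletion vector library and at -3.45 in the dnd library. The glycyl radical gene grcA (-4.66), the biofilm regulator gene bssR (-4.62), the nickel-binding protein gene nikA (-4.32), BW25113_RS03105, an enterobactin proofreading thioesterase (-4.49), and BW25113_RS08335, a dithiobiotin synthetase (-4.20), were also among the 8 lowest. In the dam operon 3 genes were called higher, the remaining reads of dam (1.32) and, though not under every alternative, aroK (1.12) and aroB (1.03), while damX (0.52), rpe (0.13), gph (0.07) and trpS (-0.06) were not past the rule.

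The dnd library was then compared with the wild type library to see how far the dam deletion strain with dnd genes stood from the reference. SOS genes were called higher in 15 of 28 cases, with a median log2 ratio of 1.06 against 1.07 in the other dam deletion library, and flu was 122.5-fold lower (log2 ratio -6.94, interval -7.18 to -6.71). The isc genes other than iscS had ratios of 0.80 to 2.07, whereas 15 of 35 iron uptake, 16 of 28 anaerobic respiration and 11 of 19 heat shock genes were called lower. Without dnd, 9 of 31 anaerobic respiration genes (median -0.32, 4 higher) and 7 of 19 heat shock genes (median -0.83, 0 higher) were called lower against wild type. Between the dnd and dam deletion vector libraries, 2 of 19 heat shock genes were called lower. Ribosomal protein genes had a median of -0.13 and general stress genes of -0.07. Of 3731 measured genes, 281 were called higher and 345 lower, together 16.8 percent, with 114 past 4-fold.

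With plasmid reads included in the total count the split was 561 higher and 205 lower, with a shift of 0.34 in the median of all genes. With FPKM values it was 496 and 203, with a shift of 0.28, and past 4-fold it was 34 and 80.

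The SOS list had 15 of 28 members higher and 0 lower (median 1.06, percentile 100), with recX (2.26), dinI (2.13), recN (1.97) and yafO (1.80) on top. Adhesion genes were lower in 8 of 13 cases and higher in 1 (median -1.28, percentile 0). After flu these were led by the fimbrial genes fimF (-3.73, from 63 to 5 reads), fimA (-2.55) and fimG (-2.09). Iron uptake genes were lower in 15 of 35 cases and higher in 1 (median -0.87, percentile 0), among them feoA (-2.90), entB (-2.46), entF (-1.91) and entA (-1.90), with 9 lower when plasmid reads were in the total count or with FPKM values. In iron-sulfur cluster assembly, 6 of 15 genes were higher and 3 lower (median 0.74, percentile 99.99), led by iscR (2.07), hscB (1.96), iscS (1.54) and iscU (2.84-fold).

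Anaerobic respiration genes were lower in 16 of 28 cases and higher in 2 (median -1.09, percentile 0). narK was 44.9-fold lower, and napF (-5.33), the nitrate reductase gene narG (-4.65) and nirB (-3.48) followed. With a summed count of at least 200, 9 were lower and 2 higher, with a median of -2.05 at percentile 0. Heat shock genes were lower in 11 of 19 cases and higher in 0 (median -1.18, percentile 0), with the chaperone genes ibpA (-2.31), clpB (-2.10) and htpG (-1.85) at the low end and dnaK 3.52-fold lower. With FPKM values 6 were lower. For ribosomal proteins 4 of 50 genes were higher (7 with plasmid reads in the total count), rpsU (1.83), rpsT (1.57), rpmH (1.41) and rpmA (1.10). The median of -0.13 (percentile 9.64) changed sign with FPKM values and when plasmid reads were included in the total. ATP synthase genes had 1 of 9 members higher and 0 lower, with a median of 0.42 at percentile 96.2. The 3 highest genes were BW25113_RS15575 (6.62), modA (4.30) and dsdA (4.26), and the 3 lowest were flu, bssR (-5.62) and narK (-5.49).

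A last count asked how many of the differences seen in the dam deletion vector library were smaller in the dnd library. The ribosomal protein gene rplA returned, from 1592 CPM in the dam deletion vector library to 3960 with dnd, against 5682 in wild type. Against wild type, the median of the ribosomal protein list was -1.33 without and -0.13 with dnd. flu, recN, dsdA and modA did not return. Of the 754 genes called in the dam deletion vector library, 424 (56.2 percent) returned, 180 of those that had been higher and 244 of those that had been lower, and 161 genes went beyond the wild type level. In the dnd library 249 genes (33.0 percent) were still called against wild type in the same direction, 127 higher and 122 lower. Against the dam deletion vector library, 317 genes (42.0 percent) were called in the reverse direction and 12 in the same direction.

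The comparisons behind the returning and reverse counts share the dam deletion vector library, so some return is given by chance. Those behind the genes still called against wild type share the wild type library. When the dnd and dam deletion vector libraries were simulated at equal levels, 0.94 percent of called genes returned with counting error alone, and 2.47, 13.2 and 34.9 percent returned with coefficients of variation of 0.1, 0.2 and 0.4 between libraries. With all 3 libraries at equal levels and a coefficient of variation of 0.4, 923.5 genes were called on average and 49.6 percent of them returned. In that simulation 321.6 genes (34.8 percent) were still called in the same direction and 323.3 (35.0 percent) were called in reverse, beside the observed 249 and 317. The highest shares among its 100 simulations were 53.9 percent returned and 38.4 percent in reverse, below the observed 56.2 and 42.0. Each gene was drawn independently there, whereas genes of a list often moved together in these libraries. The simulated range may therefore be too narrow, and the observed shares are not shown to lie beyond chance. Independent lists of the same sizes would share 58.4 genes in the same and 69.4 in the reverse direction, among 3694 genes measured in all comparisons. The lists compared here share a library and are not independent, so these are not chance levels for the observed counts. With all 3 libraries at equal levels, a coefficient of variation of 0.2 called 99.95 genes on average. The observed 754 thus lay between the settings of 0.2 and 0.4. The spread between cultures was not measured and genes were not drawn in groups. Chance between single cultures is therefore not ruled out as the source of these overlaps.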

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

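Reads on the plasmid sequences lie outside the gene comparisons and were singled out because each plasmid had reads in the libraries said to carry it and 0 in the others. The empty vector sequence, 2961 nt long, held 1727961 reads in the wild type library, which is 18.1 percent of all reads, 1163466 reads in the dam deletion vector library (10.8 percent) and 0 in the dnd library. The sequence of the dnd plasmid, 9679 nt long, held 43051.86 reads in the dnd library (0.491 percent) and 0 in both others. Scaled by plasmid length and by effective library size, the vector stood 2.30-fold higher in the wild type than in the dam deletion vector library. In the latter it stood 66.2-fold higher than the dnd plasmid in the dnd library. Both sequences carry the name pBluescript in the files, and whether each library was mapped to both is not given in the sources used here, so the zeros do not show that a plasmid was missing. The dnd plasmid is named pJTU1238 in the labels and pWHU1238 in the column headers. Each plasmid was counted as a whole, so reads of dndBCDE were not separated from those of the backbone. These differences between single libraries were not tested, and no explanation was weighed for them.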

How the results depend on the processing

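The alternatives that include plasmid reads in the scaling, and TMM over genes with a summed count of at least 50, were chosen after seeing the data. Moving the fold threshold to 1.5 gave 1542, 1646 and 1375 called genes in the 3 comparisons, in the order dam deletion vector against wild type, dnd against dam deletion vector and dnd against wild type, beside 754, 771 and 626. A threshold of 4-fold gave 96, 106 and 114, and a whole interval beyond 2-fold gave 486, 492 and 376, which follows from the thresholds themselves. At 1.5-fold, 866 genes returned, which follows from the larger number called, since the share stayed at 56.2 percent. The other 42 of 51 counts of called genes stayed within 1.5 times, between 604 and 980, 628 and 963, and 450 and 886. No gene was called in the opposite direction to the TMM result. For the scalings this was given in advance, since they moved the median of all genes by at most 0.46, less than a call needs. The split into higher and lower moved by over 10 points in 13 alternatives. Beside 352 and 402 it was 653 and 200 with total counts and 829 and 151 with plasmid reads in the total. Beside 392 and 379 it was 216 and 637, and 310 and 476, in the same order, 28 and 78 at 4-fold, and 581 and 217 for FPKM + 1, 600 and 224 for FPKM + 0.1 and 658 and 305 for FPKM without a minimum. Beside 281 and 345 it was 561 and 205 with plasmid reads in the total, 34 and 80 at 4-fold, and 496 and 203, 512 and 217 and 616 and 270 for the same FPKM settings.

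The flagella median reversed in both comparisons with the dam deletion vector library, to 0.0015 with plasmid reads in the total, and to -0.044 with total counts and -0.15 with a summed count of at least 200 for dnd against dam deletion vector. These total-count scalings shift all genes alike, by 0.46 and -0.27, and the percentiles stayed at 0.01 and 99.92. The filter of 200 leaves out the genes with low counts, and the percentiles were then 6.76 and 64.7, inside the middle 95 percent. Of 360 list medians under alternatives, 273 stayed within their counting spread, 84 moved with the same sign or were not called, and 3 reversed. The number of lists outside the middle 95 percent was 18, 13 and 14 and stayed within 1.5 times in 36 of 36 alternatives. A scaling shifts a list and its random lists alike, so the scaling alternatives gave 18, 13 and 14 again by construction. Only the changed minimum counts, prior counts and FPKM values could move these numbers. The count of returning genes stayed within 1.5 times in 8 of 9, between 363 and 523. Of 913 values of named genes, 623 stayed within the counting interval, 290 moved and 0 reversed. Only called genes could count as reversed, and no setting shifted all genes enough for that. Of 807 values of genes called with TMM, 23 were not past the rule, for 11 genes: trpS, priB, recF, mnmG, dnaN, atpD, atpG and atpC in the dam deletion vector library, and aroK, aroB and uvrD with dnd. TMM with plasmid reads moved no ratio. The motif alternatives gave no value because no genome was used here, and leaving out rRNA and tRNA gave none because no such gene was among the named ones. No paired analysis was possible because each group had 1 library. Depth limits the low genes: flgB had 4 reads in the dam deletion vector library, and its interval ran from -6.67 to -3.34.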

Other observations

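The tests that weigh explanations in this part were chosen only after the results were seen, whereas the list medians, the count of returning genes and most scalings they draw on were chosen before. The genes named outside the lists were picked for their values. The molybdate transport genes modA, modB and modC were higher in both dam deletion libraries, with a median log2 ratio of 1.73 without and 2.49 with the dnd plasmid against wild type. A run of 7 neighbouring genes of the hydrogenase-2 region, which includes BW25113_RS15575, had medians of 1.54 (range 1.27 to 6.89) and 1.96 (range 1.42 to 6.62) in the same comparisons. ilvC, the ketol-acid reductoisomerase gene, had 2001 CPM in wild type, 529 in the dam deletion vector library and 57.0 in the dnd library.

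Among multi-copy mobile elements, whose divided reads cannot be assigned to a copy, 6 genes listed as integrase and 1274 nt long had 297 reads each in wild type, 3259 in the dam deletion vector library and 3525 in the dnd library. The 9 IS5 transposase genes had 2620, 3919 and 2740 reads each, a log2 ratio of -0.05 for the dam deletion vector library against wild type. The iron-sulfur operons also stood in opposite directions without dnd. Against wild type, the isc genes other than iscS had a median of -0.82 and the suf genes 1.10 in the dam deletion vector library, and 1.47 and -0.99 in the dnd library.

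The SOS median was higher in both dam deletion libraries. Library scaling is argued against, since the lowest SOS median over the scalings and both comparisons was 0.998. A general difference of the dam deletion vector culture alone would not cover the dnd library, where the SOS median was 1.06 and ribosomal protein genes were at -0.13. That SOS median is part of the pattern itself, so it gives no separate test. A difference of the wild type culture cannot be told apart from an effect of the deletion, because only 1 wild type library was sequenced.

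With the dnd plasmid, isc genes were higher, and suf genes and 25 of 36 iron uptake genes lower. Plasmid reads counted as iscS are argued against as the source of the whole isc pattern, because the 6 other isc genes had a median of 2.21. For iscS itself these values cannot decide, since both could hold. The dam deletion vector library standing apart alone is argued against by the iron uptake median of -0.87 between the dnd and wild type libraries. Anaerobic respiration genes were also lower, at -0.71, and each group was a single culture. A difference in oxygen or iron supply of the dnd culture therefore cannot be told apart from an effect of the dnd plasmid. No library separated the dnd genes from the rest of that plasmid.

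Many differences seen in the dam deletion vector library were smaller with the dnd plasmid. Counting error is argued against, since with the dnd and dam deletion vector libraries at equal levels it returned at most 2.01 percent of called genes in simulations, against 56.2 percent observed. With all 3 libraries at equal levels it called 2.59 genes on average, of which 36.4 percent returned, against 754 genes observed. Spread between single cultures cannot be told apart from an effect of the plasmid, because the true spread was not measured. Equal groups with a coefficient of variation of 0.4 called 923.5 genes on average and returned 49.6 percent on average and 53.9 percent at most. Each gene was drawn independently in these simulations, so genes that move together could widen that range. An effect of the dnd plasmid also stays open, and its dnd genes cannot be told apart from the rest of it.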
